A study of Homo sapiens with 24 samples.

How the data were processed

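RNA was measured in 24 libraries of MCF10A cells: the lines PE and PM, each with a hairpin against GFP and hairpins A and B against CHD1, with 4 libraries in each of the 6 groups. Per the labels, all cultures received doxycycline at 50 ng/ml for 72 h, RNA was prepared with DNase on the column, and libraries were made with a poly(A) selection module and a directional kit. Per the submitters' processing notes, the authors checked reads with FastQC, trimmed them with Trim Galore 0.4.0, aligned them to the human genome GRCh38 with HISAT2 2.2.1 and made the deposited counts per gene with featureCounts. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so values of overlapping or near-identical genes are uncertain. The values were tested to be whole counts without scaling, and no column of the table lacked a sample. Group, line, hairpin and replicate number were taken from the labels. The replicate numbers were not taken to pair libraries.

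The table held 59251 genes. Names were matched to a GRCh38.p14 annotation, 57842 by current symbol and 370 by an older symbol, and 1039 were not matched. Genes with no count (17236) were left out, and edgeR's filterByExpr over the 6 groups left 20820 genes. Total counts ran from 4.14 to 93.3 M per library with a median of 49.5 M, and the median biological coefficient of variation was 18.96%, with 18 residual degrees of freedom and a median prior of 16.21. A model with 1 mean per group was fitted to all libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit and test). The contrasts were each CHD1 hairpin against the GFP hairpin in each line, their mean in each line, the difference of these effects between PM and PE, PM against PE with the GFP hairpin, and hairpin B against hairpin A. P-values were two-sided and adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. A gene counted under both hairpins when each passed in the same direction, and its change is the mean of both. For CHD1 and MYC the levels in CPM after TMM were also compared by two-sided exact permutation tests. The ± values are SDs of 4 libraries, and the 95% interval of a ratio of counts covers counting error only. Each SE is approximate: the size of the log2 change divided by the square root of the quasi-likelihood F statistic.

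The 35 gene lists, with 1020 entries of which 1019 were found in the table, were written before the data were examined, as were the contrasts, the rule for naming genes and the alternatives, with the exceptions named in the closing parts. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 35 lists per contrast. The alternative estimated the correlation for each list. Members were counted as past the threshold after adjustment over all genes and after adjustment over the list alone. Genes named in the text are CHD1, MYC and protein-coding genes with a mean of at least 5 CPM in a compared group. For the knockdown in each line these were the 8 largest rises and 8 largest falls past the threshold under both hairpins. For the difference between the lines they were the 6 largest each way with the same sign under both hairpins, and for PM against PE the 10 largest each way whose libraries do not overlap. From each list described, up to 4 members past the threshold with the largest changes could be named.

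Because the hairpins of a line share the GFP hairpin libraries, agreement was set beside 10 simulated data sets without an effect and beside 6 halvings of these libraries. The alternatives were DESeq2 size factors, library sizes alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 5 CPM in 4 libraries, the replicate number as a block, fits of the compared groups alone, a change of at least 2-fold, and leaving out each library in turn. The procedure was tested on simulated data with 100 changed genes at each size, drawn from genes with a mean of at least 1 CPM. It recovered 80% of 2-fold and 60% of 1.5-fold changes under both hairpins in PM with 1 false call, and 77% and 43% of differences between the lines with 3 false calls. Recovery of changes in weaker genes was not examined. None of 100 random lists passed at an unadjusted 0.05. The simulated genes were drawn independently of one another, whereas the estimated correlation was 0.589 for DNA replication and G1/S in the mean effect in PE. The simulation therefore does not test the preset correlation on lists whose genes vary together. For chance, library labels were regrouped into all 35 splits of 8 libraries or into 100 drawn splits where several groups were involved. XIST and Y-linked genes were left out of the text. Counts per gene do not resolve transcript isoforms or alleles, and no reads were realigned.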

Results

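Poly(A) RNA was sequenced from MCF10A cells, an established line of breast epithelial cells that is not tumorigenic. The labels name a non-transformed derivative, PE, and a MYC-transformed derivative, PM, without spelling out these letters. Each line carried a hairpin against GFP, the control, or either of 2 hairpins against CHD1, called A and B, and was treated with doxycycline at 50 ng/ml for 72 h. CHD1 is a chromatin remodelling ATPase that binds histone H3 methylated at lysine 4. The title of the series asks about a dependence of MYC-driven breast cancer on CHD1, and the data set out here are transcript counts, not measurements of viability. Each of the 6 groups held 4 libraries, 24 in all, which the labels call biological replicates without saying how the cultures were separated, so p-values measure the spread between these libraries. The total count per library had a median of 49.5 M. It was lowest, at 4.14 M, in replicate 1 of the GFP hairpin in PE and highest, at 93.3 M, in replicate 3 of hairpin A in PM. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 5.91 and 48.2, so no library was counted as a repeat of another. Of 59251 genes, 17236 had no count in any library and 20820 were tested. A count was found for 33137 genes in replicate 3 of hairpin B in PM, which stood apart from the other libraries. Replicate 4 of hairpin A in PM had a count for 19514 genes and the highest share of mitochondrial counts, 6.49%. The share of counts on the mitochondrial ribosomal RNA genes lay between 0.216% and 0.439% in the libraries with the GFP hairpin and between 0.374% and 0.586% in those with a CHD1 hairpin.

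CHD1 transcript was reduced by both hairpins in both lines. In PE its level was 78.8 ± 5.53 CPM (counts scaled to library size) with the GFP hairpin, 29.2 ± 1.2 with hairpin A and 28.1 ± 3.07 with hairpin B (SD, n = 4 each). In PM the corresponding levels were 90.0 ± 5.18, 31.04 ± 2.76 and 29.5 ± 5.40 CPM. The highest library with a CHD1 hairpin, at 34.3 CPM, lay below the lowest library with the GFP hairpin, at 74.2 CPM. The log2 changes were −1.42 and −1.48 in PE and −1.54 and −1.61 in PM, with SEs of 0.10, and the edgeR quasi-likelihood test gave adjusted p-values of 9.88e-13, 1.4e-13, 5.06e-14 and 1.2e-14. An exact two-sided permutation test gave p = 0.0286 for each, the smallest that the 70 assignments of 4 against 4 libraries allow. The depth of the knockdown did not differ detectably between the lines (log2 difference −0.12, SE 0.12, adjusted p = 0.704) or between the hairpins (adjusted p = 0.769 in PE and 0.648 in PM). In GRCh38.p14, CHD1 lies on chromosome 5 at 98853985 to 98929007 and MYC on chromosome 8 at 127735434 to 127742951, and the values are counts over each whole gene.

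MYC transcript was higher in PM than in PE and responded to 1 of the hairpins in PM. With the GFP hairpin its level was 275 ± 17.7 CPM in PE and 518 ± 27.4 in PM (log2 0.91, SE 0.06, adjusted p = 1.35e-13, exact permutation p = 0.0286). In PE it was 258 ± 8.3 CPM with hairpin A and 275 ± 24.0 with hairpin B, and neither differed from the GFP hairpin (adjusted p = 0.31 and 0.971). In PM it fell by 0.40 on the log2 scale with hairpin B, to 392 ± 12.3 CPM (adjusted p = 3.58e-06, exact permutation p = 0.0286), but not with hairpin A, at 564 ± 28.2 CPM (log2 0.12, adjusted p = 0.142). The difference between the lines in the response to hairpin B passed the test as well (log2 −0.40, SE 0.09, adjusted p = 0.00546). The counts do not tell an endogenous MYC transcript from one of a transgene.

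**Figure D1:**
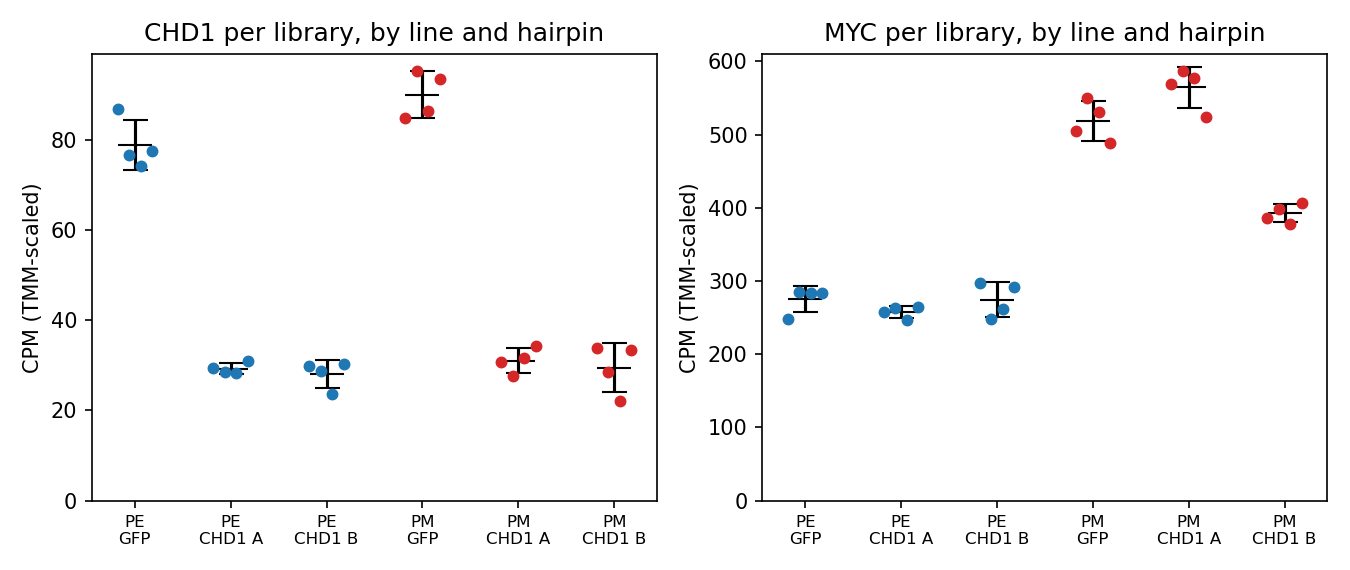
CHD1 (left) and MYC (right) transcript levels in CPM on linear axes that start at 0, for the 4 libraries (points) of each of the 6 groups, with the mean (long line) and SD (bars); PE is blue and PM red. All 16 libraries with a CHD1 hairpin lie at or below 34.3 CPM of CHD1, and MYC is higher in every PM library than in any PE library.

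The first comparison asked which transcripts changed when CHD1 was depleted in the non-transformed PE line. INHBA, which encodes the subunit of activin A, fell from 27.6 ± 9.38 CPM with the GFP hairpin to 0.584 ± 0.173 with hairpin A and 0.109 ± 0.0838 with hairpin B. FST, which encodes the activin antagonist follistatin, fell from 6.57 ± 2.56 to 0.427 ± 0.22 and 0.21 ± 0.0987 CPM. KRT17, a keratin of basal epithelial cells, fell from 76.3 ± 32.2 to 14.3 ± 3.75 and 2.29 ± 0.682 CPM, and ESRP1, a splicing regulator of epithelial cells, from 7.49 ± 3.69 to 1.76 ± 0.675 and 0.146 ± 0.0692 CPM. In the other direction, HMOX1, the inducible haem oxygenase, rose from 4.75 ± 0.47 to 42.5 ± 10.5 and 31.5 ± 8.56 CPM, and MMP2, a gelatinase, from 9.11 ± 4.95 to 36.2 ± 8.22 and 118 ± 28.7 CPM. The 8 genes with the largest mean fall in PE also included SERPINB4, SERPINB3, SERPINB2 and MAL2, at mean log2 changes of −4.95, −4.48, −4.02 and −3.64. SERPINB3 and SERPINB4 are near-identical neighbours whose reads the counting can exchange, so their separate values are uncertain. Among the 8 largest rises, PLAC8 stood at a mean log2 change of 4.25, IFITM10 at 3.58, SHISA9 at 3.55, IP6K3 at 3.29, MYLK (myosin light chain kinase) at 2.90 and EEF1A2 at 2.83. Each of these genes passed the edgeR test under both hairpins, with the larger adjusted p reaching 0.016, for SERPINB4. The call of IFITM10 was lost with limma-voom. In total, 2568 genes passed under both hairpins in the same direction, 1406 higher and 1162 lower. Hairpin A alone gave 4208 genes, 2265 higher and 1943 lower, and hairpin B 5587, 2839 higher and 2748 lower. With library sizes in place of TMM scaling, the higher share was 42.4% instead of 54.8% of the calls under both hairpins and 39.2% instead of 53.8% under hairpin A, so the balance of directions is not set by these data.

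Genes of DNA replication and repair were lower in PE cells after CHD1 knockdown, and so were inflammatory and junctional genes. Of 40 tested genes of DNA replication and the G1/S transition, 26 fell and 1 rose (30 and 1 adjusted over the list alone). PRIM1, of the DNA primase, was at a mean log2 change of −0.89 (SE 0.11) and GINS3 at −0.69 (SE 0.11). Further, 20 of 34 genes of homologous recombination and the Fanconi pathway fell and none rose (22 adjusted over the list alone). BRCA2 was at −0.97 (SE 0.12) and XRCC2 at −0.90 (SE 0.10). The camera test gave adjusted p = 1.25e-14 and 8.05e-12 for these lists, and adjusted p = 0.338 and 0.122 with an estimated correlation. In the list of G2/M and mitosis, 16 of 40 genes fell and 3 rose (19 and 4 adjusted over the list alone). ESPL1, which encodes separase, fell by 0.71 and NUF2, of the kinetochore, rose by 0.72 on the log2 scale (list adjusted p = 0.000276, and adjusted p = 0.592 with an estimated correlation). Of 30 genes of NF-kB signalling and inflammatory cytokines, 18 fell and 1 rose (20 and 1 adjusted over the list alone), with CXCL3 at −3.13 (SE 0.25) and CXCL8 at −2.27 (SE 0.17). This list gave adjusted p = 3.69e-15, and adjusted p = 0.122 with an estimated correlation. Of 22 genes of epithelial junctions, 10 fell and none rose over all genes or over the list alone. These included CDH1, which encodes E-cadherin (−3.51, SE 0.35), and the desmosomal genes PKP2 (−1.37, SE 0.14) and DSC2 (−1.01, SE 0.15). This list kept its call with an estimated correlation (adjusted p = 1.87e-10, and adjusted p = 0.0113 with an estimated correlation), and it was the 1 list of 35 in PE that did. Of 24 genes of basal mammary epithelium, 8 fell and 2 rose (9 and 3 adjusted over the list alone), with KRT17 at −3.71 and MYLK at 2.90 (adjusted p = 3.27e-07, and adjusted p = 0.122 with an estimated correlation). Among growth factor immediate-early genes 9 of 27 fell and 2 rose (10 and 2 adjusted over the list alone), with DUSP6 at −1.03 and JUNB at −0.67 (adjusted p = 4.05e-05, and adjusted p = 0.179 with an estimated correlation).

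Of the other lists that passed in PE, those named first had positive mean changes. Mesenchymal genes gave 6 rises of 28 and no fall (7 adjusted over the list alone), with MMP2 at 2.65 and S100A4 at 1.43 (adjusted p = 0.000276, and adjusted p = 0.438 with an estimated correlation). Genes of glycolysis and hypoxia gave 8 rises of 31 (11 adjusted over the list alone), with VEGFA at 0.81 (adjusted p = 3.67e-06, and adjusted p = 0.592 with an estimated correlation). Cytosolic ribosomal proteins gave 34 rises and 2 falls of 77 (35 and 4 adjusted over the list alone), with RPL26 at 0.51 and RPL10 at −0.75. Nuclear-encoded genes of oxidative phosphorylation gave 11 rises of 58 (11 adjusted over the list alone), with UQCR10 at 0.65. These lists had adjusted p = 5.42e-06 and 0.000306, and for both adjusted p = 0.592 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogenes, so their single values are uncertain. Of 29 p53 targets 5 rose and 1 fell, the same numbers as adjusted over the list alone, with CDKN1A, the cell cycle inhibitor p21, at 1.04 and TRIAP1 at 1.00. The list rose with hairpin B alone, with 20 rises and 1 fall (median 0.508, adjusted p = 7.54e-10; adjusted p = 0.191 with an estimated correlation), against 5 rises and 7 falls with hairpin A (median −0.091, adjusted p = 0.137). In the mean of the hairpins it passed at adjusted p = 0.00787 (adjusted p = 0.592 with an estimated correlation, and 0.0784 without replicate 4 of the GFP hairpin in PE). Weaker calls went towards lower values. Nucleotide and one-carbon synthesis had a mean log2 change of −0.122, with 7 falls and 2 rises of 28 (camera adjusted p = 0.0161, and 0.0887 without replicate 4 of the GFP hairpin in PE). ATF4 and amino acid stress had a mean of −0.182, with 1 fall and 1 rise of 25 (0.0429, and 0.149 without replicate 2 of the GFP hairpin in PE). Squamous differentiation had a mean of −1.18, with 1 fall of 12, that of ELF3 at −3.14 (0.0216). All 3 lost the call with an estimated correlation (adjusted p = 0.592, 0.577 and 0.122 with an estimated correlation). Each passed with 1 hairpin only, the ATF4 list with A (0.51 with B) and the others with B (0.0638 and 0.168 with A). No call was made for classical MYC targets, with 2 rises and 3 falls of 29 (3 and 4 adjusted over the list alone; adjusted p = 0.707), or for markers of immune cells (0.835) and of fibroblasts and endothelium (0.494). Among chromatin genes, SMARCA1, an ISWI remodeller, rose by 2.23 (SE 0.14), and the histone chaperone genes ASF1A and SUPT16H by 1.33 (SE 0.13) and 1.01 (SE 0.06) on the log2 scale. Their lists of CHD and ISWI remodellers and of elongation factors and histone chaperones gave adjusted p = 0.993 and 0.0931. The mitochondrial ribosomal RNA share given above was not tested. In PE its groups overlapped. Replicate 4 of the GFP hairpin, at 0.439%, lay above replicates 2, 3 and 4 of hairpin A (0.374%, 0.409% and 0.420%) and replicate 4 of hairpin B (0.429%). In PM the highest GFP hairpin library was at 0.341% and the lowest library with a CHD1 hairpin at 0.415%.

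The second comparison asked the same question in the MYC-transformed PM line. DHRS2, a short-chain dehydrogenase, fell from 8.27 ± 2.19 CPM with the GFP hairpin to 0.0486 ± 0.077 with hairpin A and 0.203 ± 0.117 with hairpin B. The chemokine transcripts CXCL3, CCL20 and CXCL8 fell as well. CCL20 went from 343 ± 79.0 to 26.9 ± 7.79 and 65.8 ± 18.0 CPM, and CXCL8 from 198 ± 47.9 to 20.1 ± 2.01 and 38.6 ± 11.7 CPM. INHBA and FST, which fell in PE, were also among the 8 largest falls in PM. INHBA went from 12.1 ± 3.98 to 0.249 ± 0.312 and 0.163 ± 0.127 CPM and FST from 5.02 ± 0.786 to 0.23 ± 0.161 and 0.379 ± 0.0815 CPM. Rises included SULF2, a heparan sulphate 6-O-endosulphatase, from 1.83 ± 0.283 to 9.37 ± 1.23 and 15.9 ± 4.12 CPM, and ABCA12, a lipid transporter of the epidermis, from 6.34 ± 1.19 to 37.0 ± 1.78 and 43.9 ± 9.37 CPM. The other falls named by the rule were CXCL3, IL13RA2 and BMP2, at mean log2 changes of −4.05, −3.94 and −2.78. The other rises were GRIN2C at 3.62, ANK1 at 3.59, CLCA2 at 3.37, HES2 at 2.88, LY6D at 2.82 and LAT2 at 2.74. The largest adjusted p among these genes under either hairpin was 2.25e-05, for ABCA12 with hairpin A. In total, 2779 genes passed the edgeR test under both hairpins in the same direction, 1345 higher and 1434 lower. Hairpin A alone gave 5778 genes, 2799 higher and 2979 lower, and hairpin B 5844, 2837 higher and 3007 lower. With library sizes in place of TMM the higher share was 53.5% instead of 48.4% under both hairpins and 56.8% instead of 48.5% under hairpin B, so here too the balance of directions is open. Among changes of at least 2-fold the hairpins went opposite ways, with 484 genes higher and 646 lower under hairpin A and 912 and 299 under hairpin B. Under both hairpins 277 were higher and 115 lower.

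Targets of p53 rose in PM after CHD1 knockdown, while cell division, repair and inflammatory genes fell. Of 29 p53 targets 16 rose and none fell (19 adjusted over the list alone), with TP53INP1 at a mean log2 change of 2.37 (SE 0.22), the secreted factor GDF15 at 2.2 (SE 0.26), CDKN1A at 1.75 (SE 0.15) and TRIAP1 at 1.62 (SE 0.07). The camera test gave adjusted p = 3.28e-18, and adjusted p = 0.0861 with an estimated correlation. Genes of DNA replication and G1/S gave 27 falls and 1 rise of 40 (29 and 1 adjusted over the list alone), with GINS3 at −0.99 and UHRF1 at −0.94 (adjusted p = 1.04e-13, and adjusted p = 0.422 with an estimated correlation). In the list of G2/M and mitosis 22 of 40 genes fell and 1 rose (24 and 1 adjusted over the list alone), with ESPL1 at −0.78 and CCNA2, cyclin A2, at −0.66 (adjusted p = 1.91e-10, and adjusted p = 0.422 with an estimated correlation). Homologous recombination and Fanconi genes gave 16 falls of 34 (19 adjusted over the list alone), with BRCA2 at −0.85 (adjusted p = 7.26e-09, and adjusted p = 0.247 with an estimated correlation). Of 30 NF-kB and cytokine genes 16 fell and none rose (17 adjusted over the list alone), with LCN2, lipocalin 2, at −2.88 beside the chemokines named above (adjusted p = 2.14e-21, and adjusted p = 0.0861 with an estimated correlation). Immediate-early genes gave 7 falls and 1 rise of 27 (9 and 1 adjusted over the list alone), with EGR1 at −1.51 and MAFF at −1.26 (adjusted p = 3.67e-08, and adjusted p = 0.0861 with an estimated correlation). Cholesterol synthesis gave 6 falls and 1 rise of 24 (6 and 2 adjusted over the list alone), with HMGCS1 at −0.65 (adjusted p = 0.00316, and adjusted p = 0.618 with an estimated correlation).

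Oxidative phosphorylation genes rose in PM in 14 of 58 cases with no fall (14 adjusted over the list alone), with NDUFB10 at 0.57 (adjusted p = 1.56e-05, and adjusted p = 0.762 with an estimated correlation). Of 25 genes of ATF4 and amino acid stress 5 fell and 1 rose over all genes and over the list alone, with SLC7A5, an amino acid transporter, at −0.75 and CEBPB at −0.63 (adjusted p = 0.0083, and adjusted p = 0.422 with an estimated correlation). Ribosome biogenesis gave 4 rises of 40 (4 adjusted over the list alone), with POLR1B, of RNA polymerase I, at 0.72 and FBL, fibrillarin, at 0.26. Its call (adjusted p = 0.0122) was lost without replicate 3 of the GFP hairpin in PM (adjusted p = 0.072) and with an estimated correlation (adjusted p = 0.81 with an estimated correlation). Basal epithelial genes gave 8 falls and 3 rises of 24, with LAMB3 at −2.12 and KRT14 at −2.16. The basal call (adjusted p = 0.0475; adjusted p = 0.769 with an estimated correlation) was lost with DESeq2 size factors (0.0547), library sizes (0.0632) or no filter (0.101), and without replicate 1 (0.078) or 2 (0.0696) of hairpin A, replicate 2 (0.0552) or 4 (0.082) of hairpin B or replicate 4 of the GFP hairpin (0.175) in PM. Classical MYC targets gave 2 rises and 4 falls of 29 (6 and 4 adjusted over the list alone) and no call (adjusted p = 0.879); HSPE1 rose by 0.78 and NCL, nucleolin, fell by 0.50 on the log2 scale. The hairpins went opposite ways in this list, with 11 rises and 5 falls with A (median 0.0643, adjusted p = 0.052) and 3 rises and 14 falls with B (median −0.167, adjusted p = 0.122). Hairpin B against A gave 18 lower and 2 higher (adjusted p = 2.24e-05, and adjusted p = 0.335 with an estimated correlation). Epithelial junction genes gave 1 fall of 22 (adjusted p = 0.372). No call was made for markers of immune cells (0.854) or of fibroblasts and endothelium (0.737). ASF1A and SUPT16H rose as in PE, by 1.20 (SE 0.12) and 1.16 (SE 0.06) on the log2 scale. None of the 11 lists past the threshold in PM kept its call with an estimated correlation. By hairpin, ribosome biogenesis, ATF4 and amino acid stress and the basal list passed with A and not with B (adjusted p = 0.175, 0.175 and 0.896), and cholesterol synthesis with B and not with A (0.895). List tests of single hairpins, here and elsewhere, were chosen after the data were seen.

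**Figure D2:**
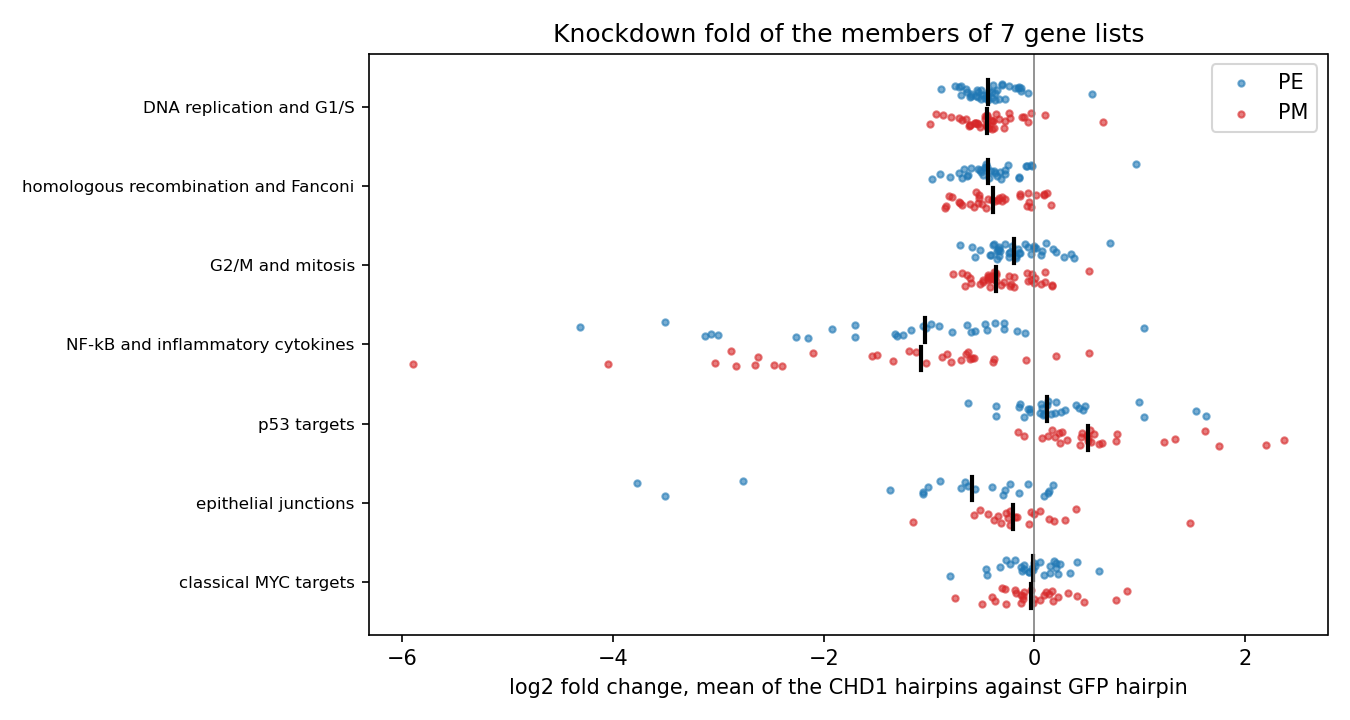
Mean log2 fold change of the CHD1 hairpins against the GFP hairpin (horizontal axis) for the members (points) of 7 gene lists in PE (blue) and PM (red), with the list median as a black line. The median of p53 targets is 0.12 in PE and 0.51 in PM, that of epithelial junctions −0.59 in PE and −0.20 in PM, and those of classical MYC targets lie close to 0, in PM as a mean of hairpins with medians of opposite sign.

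The hairpins and the lines shared many of their changes. INHBA, FST, CXCL3, CXCL8, KRT17 and BRCA2 fell and CDKN1A, TRIAP1, ASF1A and SUPT16H rose under both hairpins in both lines. Across the lines, which share no libraries, 715 genes were higher and 652 lower under both hairpins in PE and in PM, where independent lists of these sizes would share 90.8 and 80.0, and 4 genes went opposite ways. Pearson's r of the mean folds of PE and PM across genes was 0.325 and Spearman's rho 0.428. Genes are not independent replicates, so no p is given for correlations across genes. Within a line the hairpins share the GFP hairpin libraries, which alone makes their folds alike. In PE the folds of hairpins A and B had r = 0.612 and a covariance of 0.63, where simulated groups without an effect gave 0.551 and 0.26, and with the GFP libraries halved r was 0.196 and the covariance 0.331. In PM the values were r = 0.532 and a covariance of 0.518, with 0.505 and 0.206 in the simulation, and with halved libraries r was 0.278 and the covariance 0.38. Independent lists would share 308.9 higher and 256.5 lower genes between the hairpins in PE, against 1406 and 1162 observed, and 381.4 and 430.3 in PM, against 1345 and 1434. Genes called in opposite directions numbered 93 in PE and 281 in PM. The shared libraries raise these overlaps too. With halved libraries 852 higher and 674 lower genes were shared on average in PE, where independent lists would share 163 and 138. In PM these averages were 859 and 931, against 199 and 241. Opposite calls then averaged 59.7 in PE and 162 in PM.

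The third comparison tested whether the knockdown effect differed between PM and PE, by subtracting the mean effect of the hairpins in PE from that in PM. Among the genes named for the largest differences, several that fell in PE changed less or the other way in PM. ESRP1 was at 17.4 ± 0.617 CPM with the GFP hairpin in PM and at 14.6 ± 1.44 and 15.1 ± 0.798 with hairpins A and B, and its difference was 3.55 on the log2 scale (SE 0.32, adjusted p = 3.83e-08). LAD1, which encodes ladinin 1, fell in PE from 4.73 ± 2.02 to 0.634 ± 0.297 and 0.123 ± 0.134 CPM and was at 50.2 ± 6.25, 57.0 ± 6.45 and 34.3 ± 2.37 CPM in PM (difference 3.88, SE 0.35). CDH1 was at 26.02 ± 1.71 CPM with the GFP hairpin, 18.2 ± 2.90 with hairpin A and 26.8 ± 3.00 with hairpin B in PM (difference 3.27, SE 0.46), and MAL2 had a difference of 2.99 (SE 0.34). The hemidesmosomal collagen COL17A1 went from 35.1 ± 11.3 to 13.9 ± 2.64 and 2.75 ± 1.19 CPM in PE and was at 4.79 ± 2.64, 6.60 ± 2.43 and 9.63 ± 2.64 CPM in PM (difference 3.19, SE 0.45). NKX1-2, a homeobox gene, was at 2.38 ± 0.919, 6.33 ± 1.15 and 2.44 ± 0.912 CPM in PM. In PE it had only 26 counts with the GFP hairpin, 1 with hairpin A and 10 with hairpin B over 4 libraries each (0.373 ± 0.504 CPM with the GFP hairpin), so the size of its difference is not set by these data. On the other side, PLAC8 rose in PE and was at 1.63 ± 0.23, 2.22 ± 0.227 and 6.89 ± 1.66 CPM in PM (difference −2.98, SE 0.35). SMARCA1 rose in PE from 5.40 ± 0.865 to 16.9 ± 1.01 and 38.5 ± 4.00 CPM and was at 3.11 ± 0.543, 3.40 ± 0.316 and 6.21 ± 0.903 CPM in PM (difference −1.66, SE 0.18). IP6K3, RARRES1, NRG1 and CCL20 had differences of −1.85, −1.81, −1.80 and −1.71. With limma-voom the calls of NKX1-2, IP6K3 and NRG1 were lost. Taken by hairpin, NKX1-2 and CCL20 passed only with hairpin A (adjusted p = 0.285 and 0.156 with hairpin B), and IP6K3 and CDH1 only with hairpin B (0.424 and 0.093 with hairpin A). In total 819 genes differed by the edgeR test of the mean effect, 369 with a higher and 450 with a lower value in PM, and 182 under each hairpin in the same direction, 91 each way. With library sizes in place of TMM the higher share was 64.3% instead of 45.1% of the 819 and 64.1% instead of 50% of the 182, and among changes of at least 2-fold it was 75.1% and 73.2%, so the balance of directions is not set by these data. With the replicate number as a block 1623 and 411 genes differed (39.6% and 38% higher), and without the filter on low counts the second number was 291.

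Targets of p53 and genes of epithelial junctions had higher values of this difference, that is, a more positive effect in PM. Of 29 p53 targets 11 had a positive and none a negative difference over all genes (18 and 1 adjusted over the list alone), with BBC3, which encodes the pro-apoptotic protein PUMA, at 0.98 (SE 0.20) and a list median of 0.395 (adjusted p = 2.49e-15, and adjusted p = 0.0914 with an estimated correlation). By hairpin the median was 0.512 with A and 0.219 with B. Of 22 genes of the junction list 9 had a positive difference and none a negative one (9 and 1 adjusted over the list alone). TJP3 was at 2.54 (SE 0.49), beside CDH1 and ESRP1, a splicing regulator that the list also holds. The junction list kept its call (adjusted p = 2.83e-11, and adjusted p = 0.00657 with an estimated correlation), as did squamous differentiation, with 1 positive and 1 negative of 12 genes (adjusted p = 0.00052, and adjusted p = 0.0321 with an estimated correlation), and replication-dependent histones, with 3 positive of 39 (adjusted p = 0.00029, and adjusted p = 0.038 with an estimated correlation). In the squamous list GRHL3, a factor of epidermal differentiation, had a difference of 2.51 (SE 0.46) and KRT10 of −0.40, and among the histones H2BC21 was at 1.28 and H2BC12 at 0.87. The squamous list passed with hairpin B (adjusted p = 5.83e-07) and not with A (0.162). The histones passed with A and with B (adjusted p = 0.000943 and 0.00407) but with neither at an estimated correlation (adjusted p = 0.0555 and 0.0804 with an estimated correlation). Transcripts of histone genes of this kind mostly lack a poly(A) tail, and many of the genes are near-identical, so their counts after poly(A) selection are uncertain. Whether the transcripts counted here carried a tail was not tested. Basal epithelial genes gave 6 positive and no negative differences of 24 (9 and 3 adjusted over the list alone), and ribosome biogenesis 4 and none of 40 (7 adjusted over the list alone), with POLR1B at 0.42. Their adjusted p-values were 0.000598 and 2.35e-05 (adjusted p = 0.298 and 0.669 with an estimated correlation). The basal difference came with hairpin B (median 0.706, adjusted p = 2.67e-12) and had the opposite sign with A (median −0.289, adjusted p = 0.599), while ribosome biogenesis passed with A (1.02e-09) and not with B (0.43).

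Lower values of the difference were found for YAP/TEAD targets, with 8 negative and 1 positive of 22 (12 and 2 adjusted over the list alone), including TGFB2 at −1.05 and F3, tissue factor, at −0.87. Mesenchymal genes gave 5 negative differences of 28 (6 adjusted over the list alone), with SPARC at −0.60, and cholesterol synthesis 3 of 24 (7 adjusted over the list alone), with INSIG1 at −0.91. Fatty acid synthesis gave 4 of 14 (6 adjusted over the list alone), with FADS1 at −0.49 and ELOVL5 at −0.36, and interferon response genes 3 of 37 (7, with 1 positive, adjusted over the list alone), with OAS3 at −0.50. The camera test gave adjusted p = 4.62e-07, 2e-04, 4.88e-06, 0.000598 and 0.00865 for these 5 lists, and adjusted p = 0.0914, 0.307, 0.191, 0.133 and 0.11 with an estimated correlation. Glycolysis and hypoxia genes gave 2 negative differences of 31 and endoplasmic reticulum chaperones 2 of 22, with list medians of −0.362 and −0.18 (adjusted p = 1.79e-06 and 9.01e-05; adjusted p = 0.614 and 0.298 with an estimated correlation). The NF-kB list, with 3 negative differences of 30 and a median of −0.262, passed at adjusted p = 0.00865 (adjusted p = 0.698 with an estimated correlation) but not without replicate 4 of the GFP hairpin in PE (0.102) or replicate 3 of the GFP hairpin in PM (0.0817). It came with hairpin A (median −0.885, adjusted p = 5.04e-08) and had the opposite sign with B (median 0.144, adjusted p = 0.25). G2/M and mitosis, with 2 negative of 40, passed at 0.000598 (adjusted p = 0.698 with an estimated correlation) but not without the 3 libraries that stood apart (0.0535). Cytosolic ribosomal proteins, with no single gene past the threshold of 77, passed at 0.00373 (adjusted p = 0.813 with an estimated correlation) but not with library sizes alone (0.247), without those 3 libraries (0.203), without replicate 1 of the GFP hairpin in PE (0.265) or without replicate 4 of the GFP hairpin in PM (0.0564). Interferon response, G2/M and mitosis and the ribosomal proteins passed with hairpin A and not with B (adjusted p = 0.289, 0.052 and 0.217). DNA replication and G1/S genes gave no call (adjusted p = 0.81; median difference −0.0041), nor did classical MYC targets in the mean (adjusted p = 0.656). By hairpin the MYC targets passed with A on the positive side (adjusted p = 0.0486, and adjusted p = 0.683 with an estimated correlation) and had a negative median with B (−0.0291, adjusted p = 0.268).

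The fourth comparison set PM against PE with the GFP hairpin and asked what separated the lines without knockdown. CCND2, which encodes cyclin D2, was at 0.159 ± 0.0442 CPM in PE and 15.5 ± 2.64 in PM, and TIMP3, an inhibitor of metalloproteinases, at 1.33 ± 1.06 and 34.2 ± 8.43 CPM. EPHA3, an ephrin receptor, was at 0.019 ± 0.0381 CPM in PE and 5.15 ± 0.597 in PM. Lower in PM were PDPN (podoplanin), at 39.3 ± 2.94 CPM in PE and 0.827 ± 0.405 in PM, the interleukin-33 receptor gene IL1RL1, at 53 ± 13.6 and 1.08 ± 0.681 CPM, and the microtubule gene MAP1B, at 43.3 ± 10.4 and 1.42 ± 0.56 CPM. DTNA, which encodes dystrobrevin alpha, had 1 raw count in the PE libraries and 1054 in the PM libraries, a ratio relative to library size of 707.8 with a 95% interval of 126.8 to 27980 for counting error only. The other genes higher in PM by the rule were FAM184B (log2 4.87), HBA2 (4.86), HBA1 (4.14), SLC16A9 (3.77), TRIM15 (3.66) and LUM (3.63), of which HBA1 and HBA2 are near-identical copies with uncertain separate values. The other genes lower in PM were CDH11 (−7.44), FABP4 (−7.09), CYB5R2 (−5.22), PRG4 (−5.09), ACKR1 (−4.97), HP (−4.94) and GDA (−4.90). The rule itself admits only genes without overlap between the 4 PM and the 4 PE libraries. Their adjusted p in the edgeR test reached at most 0.00313, for HP. In total 5309 genes differed by the edgeR test, 2944 higher and 2365 lower in PM. The higher share of 55.5% became 48.7% with library sizes in place of TMM, and was 32.4% among changes of at least 2-fold (439 higher and 917 lower), so this balance is open as well.

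Lists of genes also differed between the lines. Of 40 ribosome biogenesis genes 39 were higher and none lower (40 adjusted over the list alone), with LYAR at a log2 change of 0.98 and NOP14 at 0.83 (adjusted p = 8.87e-27, and adjusted p = 0.0759 with an estimated correlation). Of 29 classical MYC targets 25 were higher and none lower over all genes and over the list alone, with SLC7A5 at 1.24 and FASN, fatty acid synthase, at 0.70 beside CCND2. This list kept its call (adjusted p = 1.25e-21, and adjusted p = 0.011 with an estimated correlation). Aminoacyl-tRNA synthetases were higher in 15 of 20 cases (17 adjusted over the list alone), with GARS1 at 2.99 (SE 0.07). Nucleotide and one-carbon synthesis genes were higher in 20 of 28 (20 adjusted over the list alone), with PFAS at 0.68, and heat shock genes in 16 of 18 (16 adjusted over the list alone), with HSPD1 at 0.60. Ribosomal proteins were higher in 52 of 77 cases (56 adjusted over the list alone), oxidative phosphorylation genes in 31 of 58 (34 adjusted over the list alone), with ATP5ME at 0.71, and DNA replication genes in 24 of 40 (25 adjusted over the list alone), with MCM2 at 0.49. The adjusted p-values of these 6 lists were 1.49e-12, 2.25e-10, 1.04e-07, 3.67e-08, 1.78e-07 and 9.97e-06 (adjusted p = 0.0526, 0.12, 0.156, 0.416, 0.283 and 0.416 with an estimated correlation). Homologous recombination genes were higher in 8 and lower in 1 of 34, and genes of ATF4 and amino acid stress in 13 and 1 of 25, with CBS at 2.01. Genes of the epithelial junction list were higher in 10 and lower in 2 of 22, with CDH1 at 1.63 and the splicing regulator ESRP1 at 1.37. Luminal genes were higher in 5 and lower in none of 16, with EPCAM at 2.23. Their adjusted p-values were 0.0164, 0.00137, 0.00165 and 0.0151 (adjusted p = 0.435, 0.12, 0.12 and 0.111 with an estimated correlation).

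Of 27 genes of matrix and proteases 20 were lower and 1 higher in PM (22 and 1 adjusted over the list alone), with MMP14 at −2.74 (SE 0.14), SERPINE2 at −2.81 (SE 0.18) and TIMP3 as the 1 that was higher. Antigen presentation gave 15 lower and 1 higher of 20 (16 and 1 adjusted over the list alone), with CD74 at −2.59 and PSMB9 at −2.31. Interferon response genes gave 18 lower of 37 (21 adjusted over the list alone), with OAS1 at −2.64 and OASL at −2.05. These 3 lists kept their calls (adjusted p = 1.14e-26, 4.99e-09 and 3.67e-08, and adjusted p = 4.06e-05, 0.0048 and 0.00205 with an estimated correlation). NF-kB and cytokine genes gave 13 lower of 30 (17 adjusted over the list alone), with IL1B at −3.59 and IL6 at −3.08. Mesenchymal genes gave 11 lower and 2 higher of 28 (13 and 2 adjusted over the list alone), with COL6A1 at −3.23 and FN1, fibronectin, at −2.74, and immediate-early genes 10 lower and 1 higher of 27 (12 and 2 adjusted over the list alone), with DUSP4 at −1.65. Their adjusted p-values were 1.79e-11, 1.14e-05 and 0.000157 (adjusted p = 0.111, 0.153 and 0.123 with an estimated correlation). FOXO and growth factor withdrawal genes gave 7 lower and 1 higher of 19, with PDK4 at −1.49, and replication-dependent histones 9 lower of 39 (adjusted p = 0.00176 and 0.00518; adjusted p = 0.173 and 0.0928 with an estimated correlation). Squamous genes, with 6 lower and 2 higher of 12 and S100A8 at −4.09, passed at adjusted p = 0.0115 (adjusted p = 0.0928 with an estimated correlation, and 0.0581 without replicate 2 of the GFP hairpin in PM). The basal list, with 10 lower and 3 higher of 24, passed at 0.0388 (adjusted p = 0.416 with an estimated correlation) but not without replicate 1 (0.129) or 2 (0.084) of the GFP hairpin in PE, or without replicate 1 (0.0744), 2 (0.0556) or 3 (0.0514) of the GFP hairpin in PM. Genes of G2/M and mitosis (3 higher and 3 lower of 40), targets of p53 (5 and 4 of 29) and immune cell markers (1 lower of 5) gave no call (adjusted p = 0.62, 0.62 and 0.304). Each line is represented by 1 derivative, so the comparison does not separate MYC from other differences between the lines.

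The fifth comparison asked whether knockdown in PM moved the genes that separate the lines. Among genes higher in PM than in PE, 270 fell and 286 rose under both hairpins in PM, where independent lists would give 202.8 and 190.2. This tally hides opposite tendencies of the hairpins. Among genes lower in PM, 338 rose and 243 fell, where independent lists would give 152.8 and 162.9. In the mean of the hairpins, most of the lean towards rises went with the GFP libraries of PM halved between the folds. The share of the genes lower in PM with a positive mean knockdown fold was then 51.4% (range 47.4 to 54.3) instead of 55.3%, and their median fold 0.014 (−0.0388 to 0.0544) instead of 0.0621. Of the genes higher in PM, 49.3% had a negative mean knockdown fold in PM, and 45% (40.5 to 50) with halved libraries. The fold of PM against PE and the mean knockdown fold in PM had r = −0.313 and a covariance of −0.3 across genes. The shared libraries alone gave −0.534 and −0.202 in simulated data without an effect, and with halved libraries r was −0.122 and the covariance −0.167. By hairpin the covariance was −0.208 with A and −0.392 with B, beside simulated values of −0.201 and −0.202, and −0.0556 and −0.278 with halved libraries. With hairpin A 968 genes were higher and 687 lower in both, and 801 went opposite ways; with hairpin B these numbers were 371, 327 and 1717. With halved libraries they averaged 633, 460 and 393 with A and 214, 221 and 939 with B. The median knockdown fold of the genes higher in PM was 0.115 with A and −0.0982 with B on the log2 scale, and that of the genes lower in PM −0.0769 and 0.219. With halved libraries the first were 0.152 (range 0.115 to 0.182) and −0.0786 (−0.104 to −0.0447). Those of the genes lower in PM were then −0.131 (−0.174 to −0.0841) and 0.189 (0.129 to 0.222), so the lean towards rises was largely kept with hairpin B.

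The last comparison set hairpin B against hairpin A within each line. ESRP1 was lower with hairpin B than with hairpin A in PE (log2 −3.70, SE 0.36, adjusted p = 1.73e-08) and so were MAL2 (−3.92, SE 0.35) and KRT17 (−2.64, SE 0.39), while MYLK was higher in PE (2.23, SE 0.22) and in PM (2.07, SE 0.23). MYC was lower with hairpin B than with hairpin A in PM (−0.52, SE 0.06, adjusted p = 3.75e-08) and not in PE (0.09, SE 0.06, adjusted p = 0.359). CXCL3 and IL13RA2 fell less with hairpin B in PM, by differences of 1.88 (SE 0.34) and 1.89 (SE 0.42). In total 3451 genes differed between the hairpins in PE, 1558 higher and 1893 lower with hairpin B, and 5468 in PM, 2651 higher and 2817 lower. With library sizes in place of TMM the higher share was 56.4% instead of 45.1% in PE and 58.6% instead of 48.5% in PM, and among changes of at least 2-fold it was 64.2% and 79.7%, so the balance of directions is not set by these data.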

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

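The tests of 1 hairpin alone and of a varying share of epithelial-like cells were chosen after the results were seen, as was leaving out the 3 libraries that stood apart together.

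The effect of the CHD1 hairpins differed between PM and PE by a test of the difference itself for 819 genes in the mean and for 182 under each hairpin. Of 100 regroupings of the libraries, the real groups included, only the real groups (1 of 100) gave as many genes in either test. The highest other numbers were 13 and 3. The regroupings mix GFP and CHD1 hairpins within each line, which also breaks up the knockdown effect itself. Few genes can pass in them even if both lines respond alike, so they do not decide whether the difference between the lines is chance. The genes named by the rule had differences of 3.88 (LAD1), 3.55 (ESRP1), 3.27 (CDH1), 3.19 (COL17A1) and 2.99 (MAL2), and of −2.98 (PLAC8), −1.85 (IP6K3), −1.81 (RARRES1), −1.80 (NRG1), −1.71 (CCL20) and −1.66 (SMARCA1). The value of NKX1-2, 4.10, rests on 26 counts with the GFP hairpin, 1 with hairpin A and 10 with hairpin B in PE, so its size is uncertain. MYC differed under hairpin B alone, by −0.40. Each line stands for 1 derivative, so MYC transformation cannot be separated from any other difference between PE and PM, and this stays open and untested for all of these results.

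Targets of p53 had a median difference of 0.395, that is, a more positive effect in PM; in PE the list did not rise with hairpin A (median −0.091). Without the shallow replicate 1 of the GFP hairpin in PE the median was 0.393, which argues against that library as the source. An effect of 1 hairpin alone stays open: the list passed under each hairpin at the preset correlation, with a larger adjusted p of 3.54e-05 for hairpin B, but with an estimated correlation the adjusted p was 0.0555 for hairpin A, 0.644 for hairpin B and 0.0914 for their mean. The median was 0.512 under hairpin A and 0.219 under hairpin B, and single genes passed in 14 and 3 cases.

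Epithelial junction genes had a median difference of 0.407, that is, they fell more in PE. Without the shallow library the median was 0.349, which argues against that library. An effect of 1 hairpin alone stays open: the larger adjusted p of the hairpins taken singly was 2.78e-06, for hairpin A, but with an estimated correlation it was 0.0555 for A, past the threshold no longer, and 0.00392 for B. A varying share of epithelial-like cells in the PE cultures stays open: the mean correlation of the members within groups was 0.0706, between the median of 0.0307 and the 95th percentile of 0.121 of 1000 random lists. No biological explanation can be told apart from it here.

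The other lists whose median effect differed between the lines were ribosome biogenesis (0.109), basal mammary epithelium (0.256), squamous differentiation (1.43) and replication-dependent histones (0.752) on the higher side. On the lower side were cytosolic ribosomal proteins (−0.0758), G2/M and mitosis (−0.104), endoplasmic reticulum chaperones (−0.18), interferon response (−0.18), NF-kB and inflammatory cytokines (−0.262), glycolysis and hypoxia (−0.362), cholesterol synthesis (−0.191), fatty acid synthesis (−0.254), YAP/TEAD targets (−0.447) and mesenchymal genes (−0.433). Of these 14 lists only squamous differentiation and the histones kept the call with an estimated correlation (adjusted p = 0.0321 and 0.038), and the squamous list passed with hairpin B and not with A. For a single hairpin the histones did not keep it (0.0555 with A and 0.0804 with B). The basal and NF-kB lists had opposite signs under the 2 hairpins.

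MYC in replicate 1 of the GFP hairpin in PE was at 248.5 CPM, apart from the other 3 libraries of its group, of which the nearest was at 283.5. It was the 1 such case in 36 groups tested, where chance gives about 1 in 20, and this library also had the fewest counts. Its TMM factor, 1.086, was the highest of all libraries. With library sizes in place of TMM the group ran from 270 to 291.8 CPM, with a mean of 281 instead of 275 CPM. The gap to the other libraries thus depends on the scaling.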

How the results depend on the processing

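Leaving out together the 3 libraries that stood apart was chosen after the data were seen. None of 483 results for named genes and of 64 list calls changed its sign under any alternative run for it, but the balance of higher and lower genes did turn. The 11 counts of genes stayed within 1.5 times the reported number with either other scaling, the DESeq2 test, limma-voom, the stricter filter and the fits of the compared groups alone. The fit of the compared groups alone gives no value for the mean difference between the lines, which involves all groups. The CHD1 and MYC levels moved by less than 1 SD with both other scalings.

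A change of at least 2-fold, which by construction keeps fewer genes, left 720 and 1292 genes for hairpins A and B in PE, 1130 and 1211 in PM, 395 and 392 under both hairpins in PE and PM, 257 and 71 for the difference between the lines in the mean and under both hairpins, 1356 for PM against PE, and 660 and 1031 for hairpin B against A in PE and PM. The higher share then was 39% and 54.3%, 42.8% and 75.3%, 47.8% and 70.7%, 75.1% and 73.2%, 32.4%, and 64.2% and 79.7%, in the same order. With library sizes alone it went from 54.8% to 42.4% under both hairpins in PE, from 45.1% to 64.3% for the difference between the lines and from 55.5% to 48.7% for PM against PE. The difference between the lines rose to 1623 and 411 genes with the replicate number as a block, and the second to 291 without the filter; the cause was not tested. Of 60 pairs of libraries with the same number the correlation lay between −0.0373 and 0.118. Its mean was 0.0427, against −0.0139 for pairs with other numbers, and 21 of 24 libraries correlated best with their own number. Libraries of the same number thus shared a weak component, which the main fit and the exact permutation tests left out. The column names of the counts also carry a running number. It places all libraries of 1 replicate number together, before those of the next. The labels do not say whether these libraries were also cultured or prepared together, and what the component stands for was not tested. With each list's correlation estimated, 8 of 64 list calls were left. Halving the GFP libraries moved the covariances from 0.63 to 0.331 in PE, from 0.518 to 0.38 in PM and, for PM against PE beside the knockdown, from −0.3 to −0.167, since it removes the shared libraries.

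Leaving out 1 library at a time gave 3464 to 4376 and 4726 to 5853 genes for hairpins A and B in PE, 4995 to 6061 and 4928 to 6155 in PM, 2098 to 2684 and 2346 to 2963 under both hairpins, 548 to 944 and 136 to 216 for the difference between the lines, 4297 to 5394 for PM against PE, 2561 to 3709 and 4608 to 5769 for hairpin B against A, and 63 to 69 list calls. Without the 3 libraries together the counts were 3931, 5552, 5761, 5553, 2419, 2660, 713, 133, 5136, 3924 and 4750 in the same order, and 65 list calls.

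Of 483 results for single genes the call was lost in 12 with DESeq2 size factors, 22 with library sizes, 8 with the DESeq2 test, 37 with limma-voom, 19 without the filter, 2 with the block, 296 with a change of at least 2-fold, 57 without the 3 libraries and 104 without some single library. With the stricter filter it was lost in 3 of 443, and with the compared groups alone in 10 of 397. Of the 64 list calls 1, 2, 1 and 0 were lost with DESeq2 size factors, library sizes, no filter and the block, 3 without the 3 libraries and 9 without some single library. The smallest library, with 4.14 M counts, limits what can be seen of weak transcripts in PE.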

Other observations

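The tests of greater depth and of an effect of hairpin B on the library described below, and the list tests of single hairpins and of hairpin B against hairpin A, were chosen after the results were seen.

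Hairpin B differed from hairpin A although both reduced CHD1 alike. Cholesterol synthesis was lower with B in both lines, with 16 lower and 1 higher of 24 genes in PE (adjusted p = 3.33e-19; adjusted p = 0.0298 with an estimated correlation) and 15 lower in PM (adjusted p = 4.65e-10; adjusted p = 0.0854 with an estimated correlation). IDI1 was at −1.39 and −1.33 in PE and PM. Targets of p53 were higher with B in PE for 23 of 29 genes and lower for 1 (adjusted p = 3.47e-24; adjusted p = 0.045 with an estimated correlation) and in PM for 10, with 1 lower (adjusted p = 0.000346; adjusted p = 0.449 with an estimated correlation). In PM matrix and protease genes were higher with B for 16 of 27 and lower for 2 (adjusted p = 2.18e-09; adjusted p = 0.0121 with an estimated correlation), and interferon response genes higher for 18 of 37 and lower for 3 (adjusted p = 3e-05; adjusted p = 0.0174 with an estimated correlation). Ribosome biogenesis was lower with B for 16 of 40 genes in PE (adjusted p = 6.49e-06; adjusted p = 0.618 with an estimated correlation) and for 36 in PM (adjusted p = 2.86e-18; adjusted p = 0.179 with an estimated correlation), and it rose with A in PM for 26 genes (adjusted p = 1.49e-10; adjusted p = 0.339 with an estimated correlation) but not as a list with B (adjusted p = 0.175). Effects of a hairpin beyond CHD1 were not tested, since the design holds no rescue.

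Replicate 3 of hairpin B in PM had a count for 33137 genes, among them 8926 genes nearly silent in the other libraries. No other library had a count for more than 824 such genes, where only those with a known length were counted. The 8926 genes held 60562 counts, 0.0862% of the total of replicate 3. Thinned to the smallest total it still had 22697 genes against at most 19523 in the others, which argues against greater depth, and the lowest library of its group had 18432, below the highest GFP hairpin library in PM with 18875, which argues against an effect of the hairpin. RNA of another sample is argued against as well, since the top 1% of these genes held 5.66% (95% interval 5.35 to 5.98) of the counts on them. Genomic DNA stays open: the correlation across genes of count with exonic length was 0.402 (0.391 to 0.415) over 17407 genes with a known length, against 0.037 to 0.138 in the other libraries. Few of these genes had a count in the other libraries, which by itself holds their correlations low, so the comparison with them does not decide. The value of 0.402 goes with genomic DNA, but a length is known for only 50.3% of the 8926 genes, too few for a check of length to decide. Olfactory receptor genes with a count numbered 134, or 49 after thinning, against at most 26 in any other library. The 26 were found in replicate 1 of the GFP hairpin in PE, the smallest library, and after thinning all remaining libraries had at most 13. In a principal component analysis of log CPM this GFP hairpin library also stood apart, at 176.1 on the second component against at most 31.25 in any other library.

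In the other comparisons the real groups were also the only split (1 of 35, or 1 of 100 for both hairpins together) with as many genes past the threshold. A share of 1 in 35 is the smallest that the splits of 8 libraries allow, so chance assignment is made unlikely but not excluded. The regroupings for both hairpins also mix the hairpins with each other. They test only whether the groups of a line differ at all. In fits of the 8 libraries alone the real and the highest other numbers were 3888 and 2 for hairpin A and 5064 and 0 for hairpin B in PE, 6016 and 1 for hairpin A and 5971 and 0 for hairpin B in PM, 4659 and 0 for PM against PE, and 3829 and 11 in PE and 5289 and 0 in PM for hairpin B against A. Under both hairpins they were 2568 and 27 in PE and 2779 and 825 in PM.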
